A study of Mus musculus with 16 samples.

How the data were processed

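Bulk RNA sequencing was carried out on 16 mouse libraries from YUMM1.7 tumours, a mouse melanoma line, grown to 200 to 350 mm3. The series describes the cells as sorted type 1 conventional dendritic cells (cDC1s). Per the labels, full-length cDNA was made from 1000 pg of RNA with SMART-Seq v4 and 12 cycles of PCR, and libraries were made with Nextera XT and 12 more cycles. The genotype labels gave 4 groups of 4 libraries, namely Ikbkb floxed controls, Ikbkb-deleted, Irf1 floxed controls and Irf1-deleted. The growth and treatment notes name only the Ikbkb mice, so the group of every Irf1 library rests on its genotype label. Replicate numbers follow the order of the samples in the record and pair no libraries. The labels do not say whether replicates came from separate animals, so p-values measure the spread between these libraries.

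The authors deposited 1 table of raw counts of reads per Ensembl gene, without normalization. Per the submitters' processing notes the tools were bcl2fastq 2.17.1.14, cutadapt 1.10, STAR 2.5.3a and HTSeq 0.6.1p1 with genome build mm10. The annotation release and the strand setting were not given in the sources used here. The table held 32697 genes, of which 32684 were matched to a symbol in GENCODE M21, the source of the coordinates given here, and 13 were not. Total counts per library, in order of replicate, were 22544510, 20030868, 23271467 and 16478671 in the Ikbkb controls and 21744912, 20157561, 19266660 and 20280628 in the Ikbkb-deleted libraries. They were 22234632, 18726833, 24303369 and 19206051 in the Irf1 controls and 20511322, 27433818, 19515548 and 24180056 in the Irf1-deleted libraries. PCR reads without molecular identifiers are not independent molecules, so intervals from counts alone would cover counting error only. Replicates differed by more than counting error, with a chi-square per gene of at least 44.9 in every pair of replicates of a group.

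Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with its minimum count of 10 and minimum total of 15, which left 16040 genes, and libraries were scaled by TMM. All 16 libraries entered a single quasi-likelihood fit with a mean per group. The contrasts were each deletion against its own controls, the difference between both deletions, and the Irf1 controls against the Ikbkb controls. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. TMM-scaled CPM (counts relative to the scaled library total) are given as mean ± SD over the 4 libraries of a group, and log2 fold changes carry their standard error (SE). Log2 CPM used a prior count of 2. Targeted genes, correlations and slopes were tested by exact permutation, two-sided, over all labellings or pairings. Calls shared by both deletions were counted against Fisher's exact test.

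A total of 21 gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. The lists were NF-kB pathway and target genes, type I interferon-stimulated genes, interferon-gamma-inducible GTPases and targets, DC maturation and migration, MHC class I and antigen processing, MHC class II presentation, cDC1 identity, chemokines and cytokines, pattern recognition and innate signalling, cell cycle, apoptosis regulators, cholesterol biosynthesis and uptake, and dissociation stress genes. A further 8 lists held markers of macrophages and monocytes, cDC2s, plasmacytoid DCs, T and NK cells, B cells, neutrophils, melanoma cells, and fibroblasts and endothelium. Of 455 entries, 442 were tested, and these held 416 different genes, so some genes sit in more than 1 list. Members past the threshold were counted over all genes and adjusted over the list alone.

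The groups, contrasts, tests, lists, a first set of other settings and the rule for naming genes were fixed before the data were examined. The rule named both targeted genes, and for each deletion the called genes with the largest changes among those with a mean log2 CPM of at least 3 and no overlap between the libraries of both groups, leaving out predicted genes and pseudogenes. Where no gene was called it named the 3 genes with the smallest p on each side, as values. It named 5 genes on each side for the control groups, and per list up to 4 called members or the 2 members with the highest expression. Those settings were size factors as in DESeq2 (RLE), upper-quartile scaling, no filter and a filter of 5 CPM in 4 libraries, DESeq2 1.42.0, limma voom with quality weights, a minimum 1.5-fold change, each set of 8 libraries alone, and leaving out each library in turn. Settings added after seeing the data were a cDC1 score, a T and NK cell score or 2 surrogate variables (sva 3.50.0) as covariates, a robust fit, and leaving out in each set the control library least like its group.

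The pipeline was tested on simulated data. The 200 changed genes were drawn only from those with a mean log2 CPM of at least 3, and all changed at once. In the Ikbkb comparison 25.9% of the 2-fold, 87.5% of the 4-fold and 88.9% of the 8-fold changes were recovered. The shares were 21.1%, 82.3% and 95.5% in the Irf1 comparison. With no change simulated, 0 genes and 0 lists were called. Genes were drawn independently of each other in this simulation, whereas estimated correlations within lists of the real data reached 0.769. It therefore does not show how often the list test passes by chance in these data. Nor does it show what share of changes of these sizes would be called in them, so 0 calls do not exclude such changes. Every library was used.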

Results

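RNA was sequenced in 16 libraries from YUMM1.7 melanomas, made from cells that the series describes as sorted cDC1s, the dendritic cells that cross-present tumour antigen to CD8 T cells. There were 4 groups of 4 libraries. In 1 set of 8 libraries the groups were floxed controls and mice with Ikbkb deleted, and in the other set floxed controls and mice with Irf1 deleted, with the deletion named after XCR1, a chemokine receptor of cDC1s. Ikbkb encodes IKK-beta, a kinase that activates NF-kB, and Irf1 encodes a transcription factor induced by interferons. The series title names an axis of both factors in cDC1s, so the comparisons asked which genes differed without each factor and whether these were the same genes. Libraries held 16478671 to 27433818 counts and 18468 to 22900 genes with a count. The share of mitochondrial counts ran from 0.7% to 3.15%. All values below with ± are means and SD over 4 libraries unless stated otherwise.

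The amount of cDC1 RNA varied widely between libraries, and RNA of other cells was abundant in all of them. Genes of cDC1 identity summed to 4567 ± 4832 CPM in the Ikbkb controls and 5059 ± 4651 CPM in the Ikbkb-deleted libraries. The sums were 2463 ± 917 CPM in the Irf1 controls and 2872 ± 1660 CPM in the Irf1-deleted libraries. Across the 16 libraries these genes took between 0.121% and 1.2% of the counts, a 9.84-fold range, and Xcr1 itself ran from 12.1 to 318.2 CPM. Members with high counts weigh most in this sum, so it is a rough measure of cDC1 RNA. Ppt1 ran from 278 to 2114 CPM, Irf8 from 163 to 2511 CPM and Clec9a from 0.603 to 67.6 CPM. Macrophage and monocyte genes summed to 10586 ± 1070 and 9003 ± 4195 CPM in the Ikbkb controls and Ikbkb-deleted libraries, and to 10997 ± 4993 and 8703 ± 2440 CPM in the Irf1 set. Of these sums the single gene Spp1 gave 4369 and 4269.5 CPM in the Ikbkb set and 5567 and 5131 CPM in the Irf1 set. Fibroblast and endothelium genes summed to 9778 ± 203 and 8717 ± 2812 CPM in the Ikbkb set and to 23036 ± 9021 and 18576 ± 3985 CPM in the Irf1 set. These sums reflect matrix genes above all. In the Ikbkb controls Col3a1, Sparc and Col1a2 averaged 2444, 3332 and 1870 CPM, and the endothelial genes Cdh5 and Tek 3.04 and 0.171 CPM. Over all 16 libraries the most abundant genes after mt-Cytb included the MHC class II genes Cd74 (6782 ± 5352 CPM) and H2-Ab1 (6494 ± 6435 CPM). They also included Spp1 of the macrophage list (4834 ± 1388 CPM), the collagen gene Col3a1 (4692 ± 3472 CPM) and the matrix gene Sparc (3870 ± 1056 CPM). Genes of T and NK cells summed to between 69.1 and 2207 CPM, a 31.9-fold range.

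**Figure D1:**
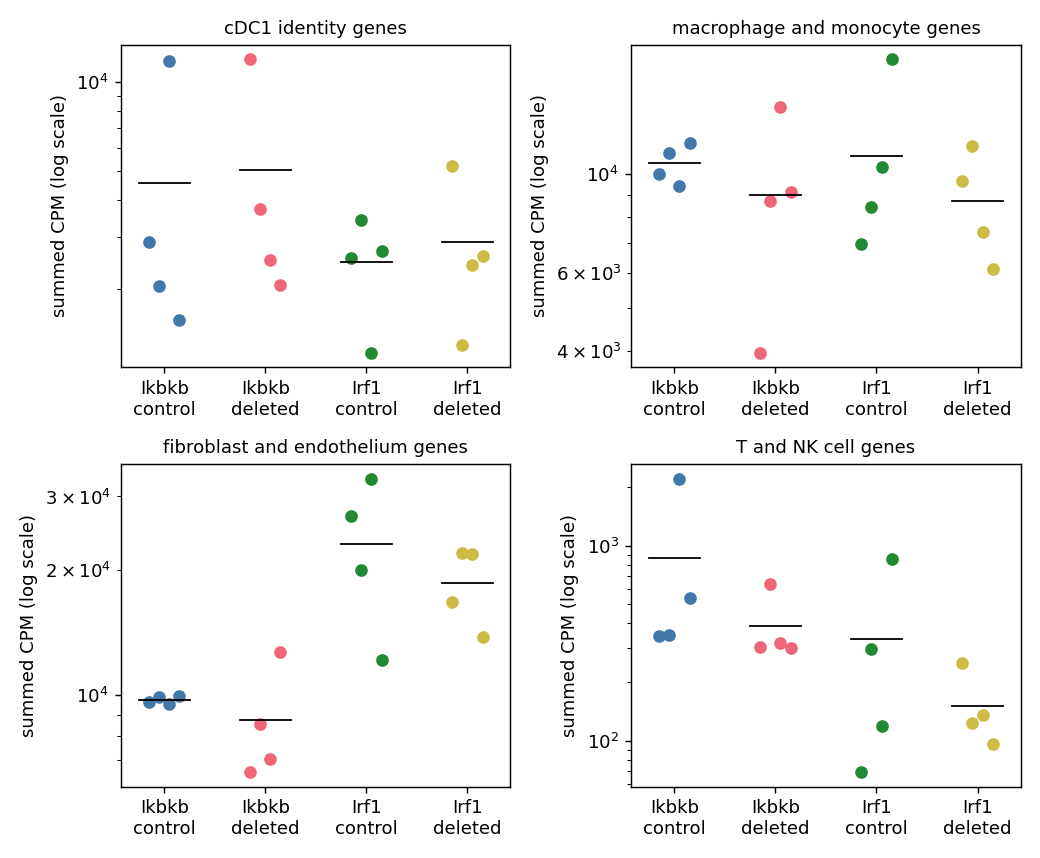
Summed TMM-scaled CPM on a log axis of cDC1, macrophage and monocyte, fibroblast and endothelium, and T and NK cell genes, with a point per library and a line at each group mean. T and NK cell genes spanned 69.1 to 2207 CPM over the 16 libraries, and fibroblast and endothelium genes averaged 9778 CPM in the Ikbkb controls and 23036 CPM in the Irf1 controls.

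The first question was whether each targeted gene was lower in the libraries labelled as lacking it. Ikbkb (ENSMUSG00000031537, mm10 chromosome 8, 22659212 to 22706589, minus strand) measured 45.1, 44.5, 120.8 and 48.6 CPM in the Ikbkb controls. In the libraries labelled Ikbkb-deleted it measured 46.3, 28.5, 37.1 and 37.8 CPM. The means were 64.8 ± 37.4 and 37.4 ± 7.25 CPM, a log2 fold change of -0.79 (SE 0.33), or 0.578-fold with a 95% interval of 0.358 to 0.934. The edgeR p was 0.0279 unadjusted and 0.988 adjusted, and an exact two-sided permutation test of the means gave 0.0857. Without control replicate 3 the log2 fold change was -0.31 (edgeR adjusted p = 0.963). Irf1 (ENSMUSG00000018899, mm10 chromosome 11, 53770014 to 53778374, plus strand) measured 141.2, 234.2, 152.4 and 268.0 CPM in the Irf1 controls. In the libraries labelled Irf1-deleted it measured 299.2, 122.8, 144.8 and 98.6 CPM, so the library labelled Irf1-deleted replicate 1 exceeded every Irf1 control. The means were 198.9 ± 61.9 and 166.4 ± 90.5 CPM, a log2 fold change of -0.26 (SE 0.40), or 0.836-fold with a 95% interval of 0.462 to 1.51 (edgeR adjusted p = 1). The exact two-sided permutation p was 0.629. Without the library labelled Irf1-deleted replicate 1 the log2 fold change was -0.70, without Irf1-deleted replicate 4 it was -0.07, without control replicate 4 it was -0.08, and the adjusted p was 1 in each case. Irf1 was 462.8 ± 290.7 CPM in the Ikbkb controls and 295.3 ± 80.8 CPM in the Ikbkb-deleted libraries, a log2 fold change of -0.65 (SE 0.40, edgeR adjusted p = 1), and -0.12 without control replicate 3, which alone held 891.8 CPM. Ikbkb was 75.5 ± 18.0 and 58.6 ± 18.2 CPM in the Irf1 controls and Irf1-deleted libraries, a log2 fold change of -0.37 (SE 0.32, edgeR adjusted p = 1). It was -0.19 without Irf1 control replicate 4 and -0.53 without the library labelled Irf1-deleted replicate 1. The labels do not state which exons were floxed, so gene-level counts may hold reads outside the deleted exons and may not show the deletion.

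**Figure D2:**
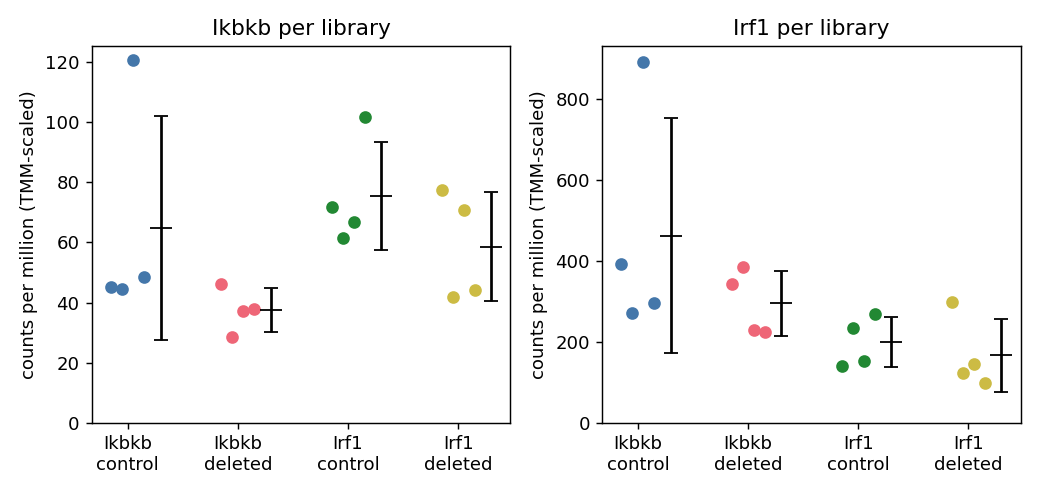
TMM-scaled CPM of Ikbkb and Irf1 in each library, by group, with bars for the mean and lines for the SD over 4 libraries. Irf1 was 299.2 CPM in the library labelled Irf1-deleted replicate 1 and at most 268.0 CPM in the Irf1 controls.

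Deletion of Ikbkb was compared with its floxed controls to ask which genes differed without IKK-beta in these libraries, which held RNA of other cells beside that of cDC1s. Type I interferon-stimulated genes, the antiviral response genes, were the list with the smallest camera p. All 34 measured members had a lower mean in the deleted libraries, with a median log2 fold change of -0.80 (adjusted p = 5.14e-12 at the preset correlation, adjusted p = 0.747 with an estimated correlation). Among them, the RNA sensor gene Ddx58 was 44.2 ± 12.8 CPM in controls and 24.4 ± 3.87 CPM in deleted libraries (log2 fold change -0.85, SE 0.24). Ifit3 averaged 102.9 and 35.2 CPM (-1.55, SE 0.46), and its paralog Ifit3b, with which it can share reads, averaged 32.4 and 10.7 CPM (-1.59, SE 0.43). These 3 members passed adjusted over the list alone, at 0.0415 for Ddx58 and Ifit3b and 0.0459 for Ifit3, and 0 members passed over all genes. Interferon-gamma-inducible genes, which include the Gbp and Irg GTPases, had a median of -0.82 with 27 of 29 members lower (adjusted p = 4.18e-07, and 0.747 with an estimated correlation). Markers of T and NK cells, which are other cells, moved with them, at a median of -1.01 with 19 of 19 members lower (adjusted p = 0.00346, and 0.747 with an estimated correlation), and summed to 860 ± 903 CPM in controls and 388 ± 164 CPM in deleted libraries.

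No single gene passed the threshold for the Ikbkb deletion. Among 16040 genes edgeR called 0, with 769 at an unadjusted p under 0.05 (297 higher, 472 lower) against 802 expected by chance, and a smallest adjusted p of 0.781. Without Ikbkb-deleted replicate 2 it called 1. Limma voom also called 0, and DESeq2 called 38 (9 higher, 29 lower), of which 32 had a count of 0 in at least 2 of the 8 libraries and 5 had none. The rule for genes without a call named Tbc1d32, a cilium gene, at 2.41 ± 1.76 CPM in controls and 19.5 ± 7.37 CPM in deleted libraries (log2 fold change 3.01, SE 0.55, edgeR adjusted p = 0.781). It named Kdm4b, a histone demethylase gene, at 30.5 ± 8.79 and 9.83 ± 1.28 CPM (-1.63, SE 0.32, adjusted p = 0.781). Further names were the Hippo kinase gene Lats2 at 13.9 ± 5.38 and 5.45 ± 2.04 CPM (-1.35, SE 0.31) and Nucb2 at 44.8 ± 4.48 and 27 ± 0.356 CPM (-0.73, SE 0.17). Slc8a1, a sodium-calcium exchanger gene, was 4.22 ± 2.84 and 21.1 ± 10 CPM (2.32, SE 0.60), and Gatc was 25.4 ± 6.48 and 41.9 ± 5.82 CPM (0.72, SE 0.20). DESeq2 called Tbc1d32, Kdm4b, Lats2, Nucb2 and Slc8a1, and edgeR did not. Libraries of both groups did not overlap for 273 genes, 1.7% of those tested, where chance gives 2.86%.

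Of the 21 lists, 11 passed for the Ikbkb deletion at the preset correlation, and 0 passed with an estimated correlation (adjusted p = 0.747 for each of the 11) or with fry (0.789 for each). All 34 other splits of the same libraries into equal groups also put at least 1 list past the threshold at the preset correlation. Lower lists besides those named were DC maturation (median -0.50, adjusted p = 0.0154, 31 of 33 members lower), chemokines and cytokines (-0.46, 0.00702, 24 of 27) and MHC class I (-0.31, 0.0276, 20 of 24). Dissociation stress genes (-0.29, 0.0276, 20 of 21), macrophage markers (-0.46, 0.0154, 15 of 18) and B cell markers (-1.20, 0.00168, 9 of 10) were also lower. Cell cycle genes (0.15, 0.0154, 28 of 32) and cholesterol genes (0.17, 0.0332, 18 of 21) were higher. NF-kB pathway and target genes, the genes closest to IKK-beta, had a median of -0.32 (adjusted p = 0.189), and of 0.25 (0.0752) without control replicate 3. Nfkbia, a feedback inhibitor of NF-kB, was 872.7 ± 328 CPM in controls and 776.2 ± 119 CPM in deleted libraries (-0.17, SE 0.23). Medians were 0.03 for cDC1 identity (0.189), 0.01 for MHC class II (0.681), -0.11 for pattern recognition (0.207) and -0.10 for apoptosis regulators (0.704), and the first 2 ran from -0.85 to 1.21 and from -0.64 to 1.09 when single libraries were left out. Markers of cDC2s (-0.28, 0.433), plasmacytoid DCs (-0.55, 0.433), neutrophils (0.05, 0.903), melanoma cells (-0.21, 0.478) and fibroblasts and endothelium (-0.16, 0.352) did not pass. Besides the type I interferon list, 0 members passed over all genes and 0 adjusted over the list alone in every list.

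Many of these list differences depended on control replicate 3, tested here at the preset correlation. Its cDC1 identity genes summed to 11768 CPM, where those of control replicates 1, 2 and 4 summed to 2882.5, 2049 and 1567.5 CPM. Among the deleted libraries they summed to 11956 CPM in replicate 1 and to at most 3712 CPM in the others. Leaving out control replicate 3 thus left Ikbkb-deleted replicate 1 without a control of like cDC1 RNA, and leaving out the latter did the reverse. Shifts of medians in these fits cannot be told apart from that imbalance. Without control replicate 3, the type I interferon median was -0.25 (adjusted p = 0.00272) and the interferon-gamma median -0.40 (0.0277). Without it, DC maturation (0.21, 0.539), MHC class I (0.09, 0.745), stress genes (0.06, 0.798), chemokines (-0.07, 0.732), cell cycle (0.03, 0.784), cholesterol (0.23, 0.154), T and NK cells (-0.10, 0.602) and B cells (-0.60, 0.149) no longer passed. Without Ikbkb-deleted replicate 2 the interferon medians were -1.21 and -1.27, and cell cycle (0.121) and cholesterol (0.109) did not pass. Without Ikbkb-deleted replicate 1, macrophage markers (-0.17, 0.799), cholesterol (0.10, 0.522) and cell cycle (0.0505) did not pass, while the medians of DC maturation (-0.94), MHC class I (-0.52) and stress genes (-0.53) were larger in size. Without Ikbkb-deleted replicate 3, DC maturation (0.206), MHC class I (0.643) and stress genes (0.252) did not pass, while the medians of macrophage (-0.85) and cholesterol genes (0.30) were larger. Without Ikbkb-deleted replicate 4, DC maturation (0.226), MHC class I (0.2), stress genes (0.154), chemokines (0.0504), cell cycle (0.0504) and cholesterol (0.0504) did not pass. Without control replicate 2, stress genes (0.0536), macrophage markers (0.102) and cholesterol (0.157) did not pass and the MHC class I median was -0.51. Without control replicate 1 the medians of MHC class I (-0.50) and stress genes (-0.48) were larger in size.

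Lists that did not pass in the Ikbkb deletion also moved with single libraries, at the preset correlation. Without control replicate 3, Ikbkb-deleted replicate 1 had no control of like cDC1 RNA. In that fit cDC1 identity (1.21, 1.15e-05) and MHC class II genes (1.09, 0.0182) passed with positive medians. Without the same library the medians of pattern recognition genes (0.16, 0.49), apoptosis regulators (0.11, 0.154), plasmacytoid DC (0.04, 0.798), cDC2 (0.01, 0.798) and melanoma markers (0.08, 0.602) turned positive. NF-kB genes passed with negative medians without control replicate 4 (-0.52, 0.00288) and without Ikbkb-deleted replicate 1 (-0.55, 0.0149), as did pattern recognition genes (-0.20, 0.0324 and -0.44, 0.0277). Without Ikbkb-deleted replicate 1 the medians of cDC1 identity (-0.85, 0.278) and MHC class II genes (-0.64, 0.345) were negative. Identity genes of cDC1s passed without Ikbkb-deleted replicate 3 (0.27, 0.0294) and replicate 4 (0.28, 0.00616), and fibroblast and endothelium markers without replicate 4 (-0.54, 0.0311). Neutrophil medians ran from -0.40 to 0.30 and melanoma medians from -0.57 to 0.61, and neither list passed without any 1 of the 8 libraries.

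**Figure D3:**
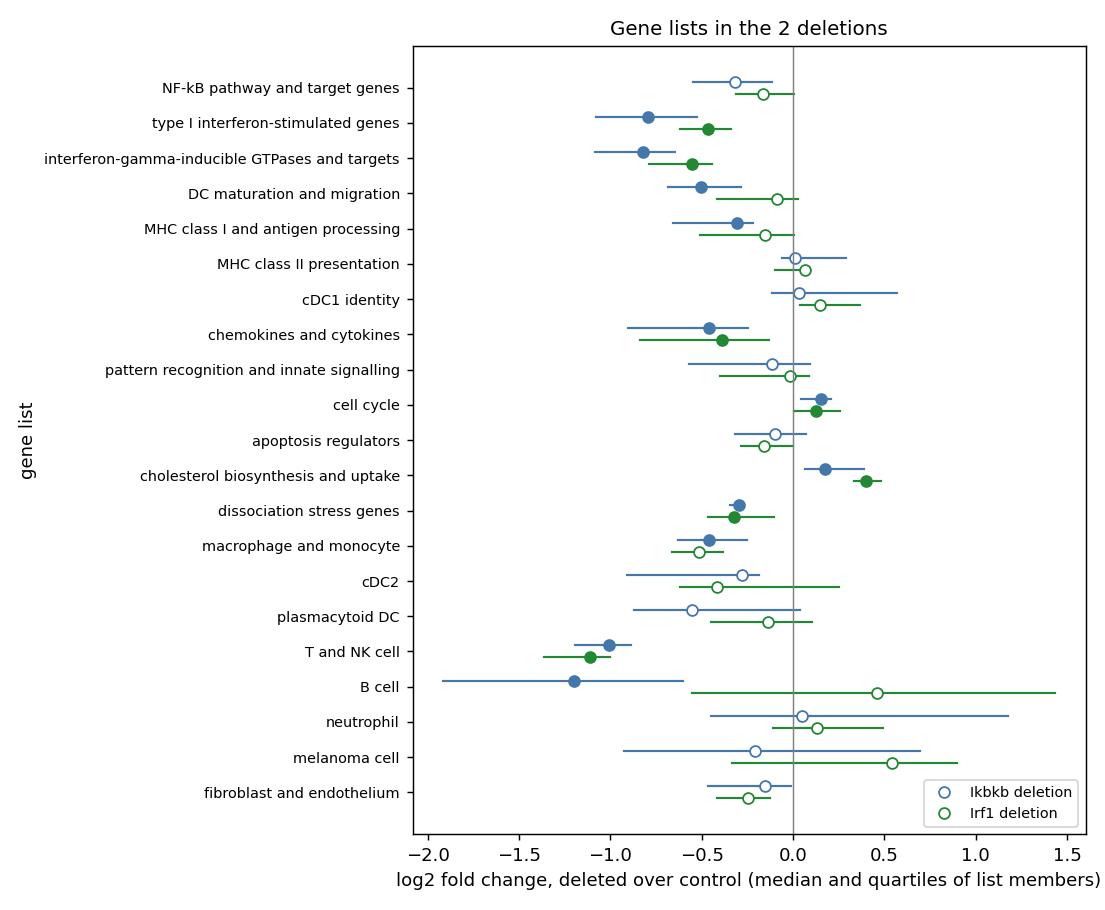
Median log2 fold change (dot) and quartiles (line) of the members of the 21 gene lists in the Ikbkb (blue) and Irf1 (green) deletions, with filled dots for an adjusted camera p under 0.05 at the preset correlation. Type I interferon-stimulated genes had medians of -0.80 and -0.47, and 0 lists passed with an estimated correlation.

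Deletion of Irf1 was compared with its floxed controls to ask which genes differed without IRF1 in libraries that likewise held RNA of other cells. Interferon-gamma-inducible genes had a median log2 fold change of -0.56 with 28 of 29 members lower (adjusted p = 4.88e-05 at the preset correlation, 0.855 with an estimated correlation). Type I interferon-stimulated genes had a median of -0.47 with 33 of 34 members lower (adjusted p = 1.09e-05, and 0.855 with an estimated correlation). Ddx58 was 83.0 ± 12.1 CPM in controls and 50.1 ± 13.5 CPM in deleted libraries (log2 fold change -0.73, SE 0.24, edgeR adjusted p = 1), and Irf7, a transcription factor gene of the type I response, was 289.8 ± 96.2 and 223.6 ± 74.7 CPM (-0.37, SE 0.55). Irgm1, an interferon-inducible GTPase gene, was 215.3 ± 58.1 and 209.5 ± 49.5 CPM (-0.04, SE 0.38). Cholesterol genes were higher, at a median of 0.40 with 20 of 21 members positive (adjusted p = 2.05e-05, and 0.855 with an estimated correlation). Cyp51, an enzyme of that pathway, was 75.8 ± 22.5 and 118.5 ± 43.3 CPM (0.64, SE 0.30). Markers of T and NK cells again moved with the interferon lists, at a median of -1.11 with 18 of 19 members lower (adjusted p = 0.0121, and 0.855 with an estimated correlation), and summed to 334 ± 358 CPM in controls and 151 ± 68.0 CPM in deleted libraries.

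For the Irf1 deletion edgeR also called 0 genes, with a smallest adjusted p of 1. At an unadjusted p under 0.05 there were 419 (224 higher, 195 lower), fewer than the 802 expected by chance. Limma voom called 0, and DESeq2 called 6, all higher, namely Trp63, Fgb, Krt14, Fcgbp, Dsp and Cldn3. Of these 6, 5 had a count of 0 in at least 2 of the 8 libraries. The keratin gene Krt14 measured 572 CPM in Irf1-deleted replicate 3, 46.6 CPM in the library labelled Irf1-deleted replicate 1 and at most 1.71 CPM in every other library. The naming rule gave the splicing gene Prpf4 at 29.9 ± 5.87 and 52.1 ± 14.9 CPM (log2 fold change 0.80, SE 0.23), the tubulin gene Tubb3 at 11 ± 4.75 and 34.6 ± 26.1 CPM (1.66, SE 0.48) and Eif2b4 at 44.0 ± 6.82 and 63.6 ± 5.31 CPM (0.53, SE 0.15). On the lower side it gave Khdc4 at 53.9 ± 3.72 and 33.0 ± 2.62 CPM (-0.71, SE 0.19), Leng8 at 75.4 ± 22.9 and 36.5 ± 8.85 CPM (-1.05, SE 0.33) and the protease gene Adamts10 at 35.8 ± 13.0 and 18.0 ± 3.12 CPM (-0.99, SE 0.31). The edgeR adjusted p was 1 for each of the 6. Libraries of both groups did not overlap for 464 genes, 2.89% of those tested, where chance gives 2.86%.

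Of the 21 lists, 7 passed for the Irf1 deletion at the preset correlation, and 0 passed with an estimated correlation (adjusted p = 0.855 for each of the 7) or with fry (0.892 for each). All 34 other splits of these libraries into equal groups likewise put at least 1 list past the threshold at the preset correlation. Besides those named, chemokines and cytokines (median -0.39, adjusted p = 0.0121, 23 of 27 members lower) and dissociation stress genes (-0.32, 0.000781, 20 of 21) were lower and cell cycle genes (0.13, 0.0219, 24 of 32) higher. Medians that did not pass were -0.17 for NF-kB genes (0.328), -0.09 for DC maturation (0.153), -0.16 for MHC class I (0.0766), 0.06 for MHC class II (0.937) and 0.15 for cDC1 identity (0.427). Pattern recognition genes (-0.02, 0.421) and apoptosis regulators (-0.16, 0.328) did not pass either. Markers of macrophages (-0.51, 0.245), cDC2s (-0.42, 0.534), plasmacytoid DCs (-0.14, 0.439), B cells (0.46, 0.354), neutrophils (0.13, 0.245), melanoma cells (0.54, 0.937) and fibroblasts and endothelium (-0.25, 0.153) did not pass. In every list 0 members passed over all genes and 0 adjusted over the list alone.

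At the preset correlation the interferon lists of the Irf1 deletion depended on control replicate 4, without which the interferon-gamma median was -0.24 (adjusted p = 0.0677) and the type I median -0.25 (0.0214). Without that library chemokines (0.03, 0.953), cell cycle (0.03, 0.953), stress genes (-0.02, 0.225) and T and NK cells (-0.09, 0.953) did not pass. Without the library labelled Irf1-deleted replicate 1 the interferon-gamma median was -1.18 and that of chemokines -0.74, and cell cycle (0.0588) did not pass. Without Irf1-deleted replicate 4 the medians of interferon-gamma genes (-0.36) and stress genes (-0.20) were smaller in size, and chemokines (0.195), cell cycle (0.178) and T and NK cells (0.225) did not pass. Without Irf1-deleted replicate 3, chemokines (0.0611) and cell cycle (0.114) did not pass, and without Irf1-deleted replicate 2 chemokines (0.0615) and T and NK cells (0.0869) did not and the cholesterol median was 0.60. Without control replicate 2, chemokines (0.102) and T and NK cells (0.216) did not pass. The medians were -0.61 for chemokines without control replicate 1 and 0.08 for cell cycle genes without control replicate 3. At the preset correlation alone, cholesterol genes passed without each of the 8 libraries in turn, with medians of 0.27 to 0.60.

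Single libraries also moved the lists that did not pass in the Irf1 deletion, at the preset correlation. Without control replicate 4 the medians of macrophage (0.26, 0.162) and cDC2 markers (0.20, 0.649), NF-kB genes (0.05, 0.953), DC maturation (0.04, 0.953), pattern recognition (0.07, 0.953) and apoptosis regulators (0.00, 0.978) turned positive. Without that library neutrophil markers (1.102, 0.0432) and fibroblast and endothelium markers (-0.40, 0.00295) passed. Without the library labelled Irf1-deleted replicate 1, NF-kB genes (-0.43, 0.0227), DC maturation (-0.54, 0.00195), MHC class I (-0.60, 0.000794), pattern recognition (-0.48, 0.026) and neutrophil markers (0.39, 0.0227) passed. The medians of cDC1 identity (-0.29, 0.293) and MHC class II genes (-0.29, 0.294) were then negative. Without control replicate 3, DC maturation (-0.37, 0.00176) and MHC class I (-0.34, 0.00811) passed, and cDC1 identity (-0.12, 0.3) and MHC class II (-0.23, 0.126) were negative. MHC class I (-0.25, 0.0384) and macrophage markers (-0.85, 6.8e-05) passed without control replicate 1, where the MHC class II median was -0.08 (0.633), and cDC1 identity genes (0.41, 0.00898) passed without Irf1-deleted replicate 2. Melanoma medians ran from -0.12 to 0.95, and that list did not pass in any of these 8 fits.

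T and NK cell markers and interferon-gamma-inducible genes were set against each other because T and NK cells are a source of interferon-gamma, in a relation chosen after the group values were seen. In the 8 libraries of the Ikbkb set, the mean log2 CPM of both lists, which share no gene, correlated at r = 0.911 (exact two-sided permutation p = 0.00211, adjusted p = 0.00422) and rho = 0.929 (exact p = 0.00223, adjusted p = 0.00446). Without control replicate 3 and Ikbkb-deleted replicate 2, the libraries farthest from the median, r was 0.661 (exact p = 0.132, n = 6). The relation in this set was weaker and did not pass without those libraries, and 6 libraries are few to test it. In the Irf1 set r was 0.931 (exact p = 0.000248, adjusted p = 0.000992) and rho 0.952 (exact p = 0.00114, adjusted p = 0.00446), and without control replicates 1 and 4 r was 0.975 (exact p = 0.00278, n = 6). About the group means r was 0.885 and 0.928. The family held 4 relations, the others being Irf1 against the cDC1 genes in each set. No other list was set against the interferon-gamma list, so the values do not show that the relation is particular to T and NK cells.

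**Figure D4:**
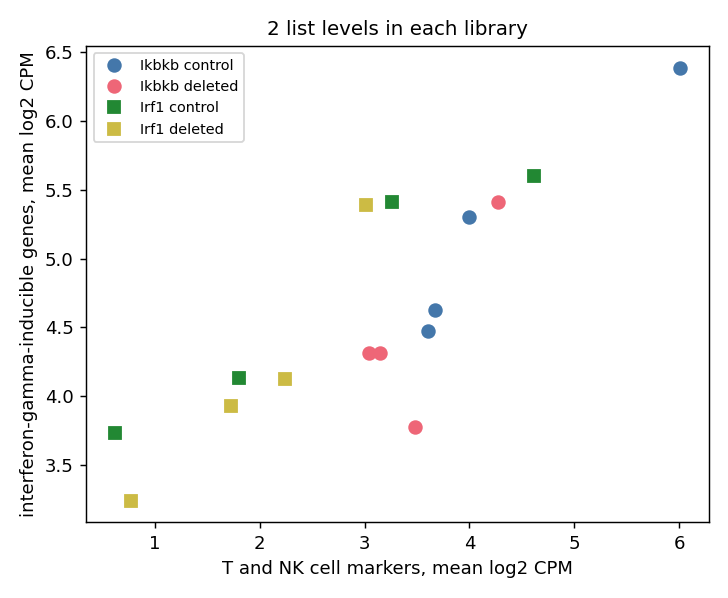
Mean log2 CPM of interferon-gamma-inducible genes against mean log2 CPM of T and NK cell markers in the 16 libraries, with a point per library and a symbol per group. Within the Ikbkb set r was 0.911 and within the Irf1 set 0.931.

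The next comparison asked whether both deletions changed the same genes, with no library shared between them. Genes with the smallest p in both included Ddx58, at log2 fold changes of -0.85 and -0.73 for the Ikbkb and Irf1 deletions. The others were Akap8l (-0.77 and -0.58), the ubiquitin ligase gene Shprh (-0.75 and -0.73), Nifk (0.35 and 0.36), Lrrc28 (0.79 and 0.70) and the helicase gene Dhx32 (0.48 and 0.63), none of which passed. With 0 calls by edgeR in either, 0 were shared. At an unadjusted p under 0.05, 17 genes were lower in both, against 5.74 expected from 472 and 195 (Fisher's exact p = 6.61e-05), and 7 were higher in both, against 4.15 expected from 297 and 224 (Fisher's exact p = 0.201). Genes are not independent replicates, so these p-values describe an overlap across genes. Across the 16040 genes both fold changes correlated at r = 0.089 and rho = 0.156, with the same sign for 56.9%. For the 10017 genes with a mean log2 CPM of at least 3, r was 0.245 and rho 0.239.

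A test of the difference between both deletions called 0 genes with edgeR, 0 with limma voom and 12 with DESeq2, of which 9 had a count of 0 in at least 2 libraries. With edgeR 455 genes had an unadjusted p under 0.05 (238 higher, 217 lower), fewer than the 802 expected by chance. Without Irf1 control replicate 3 edgeR called 1. The genes with the smallest p were Tbc1d32 (difference in log2 fold change 3.39, SE 0.74), Khdc4 (1.19, SE 0.27) and Dcun1d2 (1.17, SE 0.33). On the other side they were Kdm4b (-2.27, SE 0.44), Car13 (-1.02, SE 0.27) and the keratin gene Krt5, which was near 0 in most libraries and 160 CPM in Irf1-deleted replicate 3. B cell markers were the 1 list past the threshold, with a median difference of -1.52 and 10 of 10 members negative (adjusted p = 0.00424, and 0.96 with an estimated correlation). They summed to 430 ± 427 and 132 ± 42.9 CPM in the Ikbkb controls and deleted libraries and to 65.9 ± 38.3 and 75.3 ± 56.8 CPM in the Irf1 set. The immunoglobulin gene Igkc reached 625 CPM in Ikbkb control replicate 3.

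The floxed control groups were compared with each other to show how far the sets differ apart from the deletions. Genes of the NF-kB and immediate-early responses were among those lower in the Irf1 controls, and a collagen gene among those higher. Nfkbia was 872.7 ± 328 CPM in the Ikbkb controls and 263 ± 55.8 CPM in the Irf1 controls (log2 fold change -1.73, SE 0.24, edgeR adjusted p = 0.00391), and the immediate-early gene Fos was 2008 ± 579 and 877.7 ± 214 CPM (-1.19, SE 0.25). Col3a1 was 2444 ± 278 and 8397 ± 4283 CPM (1.78, SE 0.35). These 3 were chosen from the lists after their values were seen, and Fos is in the list of dissociation stress genes. By the rule, Tuba1a (938.9 ± 142 and 327.6 ± 32.5 CPM, -1.52, SE 0.19), Cyc1 (-1.18), Ube2d3 (-1.09), Ppp1ca (-1.37) and Sertad1 (-1.36) were the lower genes with the smallest p. The higher ones were Zfp362 (9.92 ± 1.05 and 34.2 ± 3.56 CPM, 1.78, SE 0.23), Npr2 (2.18), Col15a1 (2.81), Igfbp7 (2.07) and Itga1 (1.99), and the edgeR adjusted p was 0.00391 for each of the 10. In all, edgeR called 2018 genes (1081 higher, 937 lower), limma voom 4130 and DESeq2 3171.

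Without Irf1 control replicate 3 the controls differed in 782 genes, without replicate 2 in 850 and without replicate 1 in 1180. Without Ikbkb control replicate 2 the count was 1067 and without replicate 1 it was 1342. Of the 2018 genes, 98.9% had the same sign between both deleted groups, against 77.7% of all genes tested. Of the 21 lists, 9 passed at the preset correlation, 0 with an estimated correlation (lowest adjusted p = 0.49) and 3 with fry. DC maturation genes had a median of -1.27 (adjusted p = 7.86e-08, 7 lower over all genes and 14 adjusted over the list alone). Stress genes (-1.04, 1.96e-07, 14 and 14), chemokines (-0.99, 6.8e-05, 3 and 4 lower, with 1 higher each way), NF-kB genes (-0.99, 0.00102, 5 and 6), MHC class I (-0.76, 0.00128, 3 and 5) and cholesterol genes (-0.69, 5.03e-06, 5 and 6) were lower, with counts over all genes and over the list alone in that order. T and NK cell (-1.32, 8.03e-05, 0 and 0) and B cell markers (-2.51, 0.00599, 2 and 5) were lower, and fibroblast and endothelium markers were higher (1.42, 5.67e-06, 8 and 10). With an estimated correlation the adjusted p was 0.722 for NF-kB genes and MHC class I, 0.547 for chemokines, 0.671 for T and NK cells and 0.49 for the other 5. Stress genes (0.0251), cholesterol genes (0.0474) and fibroblast and endothelium markers (0.00247) passed with fry. Of the remaining medians, -0.30 was that of type I interferon genes (0.578), -0.51 that of interferon-gamma genes (0.0704), -0.94 that of MHC class II (0.0689) and -0.92 that of cDC1 identity (0.151). Pattern recognition (-0.31, 0.279), cell cycle (-0.07, 0.622) and apoptosis genes (-0.31, 0.115) did not pass, nor did markers of macrophages (-0.49, 0.115), cDC2s (0.00, 0.506), plasmacytoid DCs (0.14, 0.667), neutrophils (1.18, 0.622) and melanoma cells (0.61, 0.359). The labels give no line, day or sequencing run, so these cannot be told apart from the set.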

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

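In this part, the tests of the T and NK cell score, of the slopes on cDC1 genes and of a wrong label were chosen only after the results were seen, and so was the reading of the planned fits without 1 library as a test of a single unusual control.

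In groups of 4, a library stood out when its gap to the nearest other library took nearly the whole range of the group, and chance gives that in about 1 in 20 groups. Among library measures 3 of 20 groups held such a library where 1 is expected, among list levels 9 of 84 where 4.2 are expected, and among named genes 14 of 296 where 14.8 are expected. Of these 26, 11 were Ikbkb control replicate 3 and 3 were Irf1 control replicate 4. Ikbkb control replicate 3 was the least like its group, with a mean correlation of 0.872 where the other controls had at least 0.898 (gap over range 0.929). It was high in MHC class I (0.905), MHC class II (0.851), pattern recognition (0.93) and T and NK cell genes (0.837) and low in cell cycle genes (0.974). Among genes it was high in Ikbkb (0.912), H2-D1 (0.942), Cd74 (0.847) and Cxcl16 (0.961) and low in Ube2d3 (0.842). Irf1 control replicate 4 had 2.93% mitochondrial counts where the nearest other had 1.62% (0.845), a low correlation with its group (0.893) and a high level of Leng8 (0.835).

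The library labelled Irf1-deleted replicate 1, whose Irf1 exceeded that of every Irf1 control, was high in MHC class I genes (0.897) and Irgm1 (0.83). Irf1-deleted replicate 4 was low in dissociation stress genes (0.935) and plasmacytoid DC markers (0.882) and high in Cdk1 (0.872), and Irf1-deleted replicate 3 was high in Tmem173 (0.849). Ikbkb-deleted replicate 3 was low in cell cycle genes (0.849), Jun (0.841) and Dhx32 (0.916). Ikbkb-deleted replicate 2 was high in Kdm4b (0.895), and Ikbkb-deleted replicate 4 was high in Col3a1 (0.872) and in Krt5 (1), which was near 0 in all 4 libraries of that group. The change in B cell markers differed between both deletions, with a median difference of -1.521 in log2 fold change by camera at the preset correlation and not with an estimated correlation (adjusted p = 0.96).

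Interferon-inducible lists were lower in both deletions at the preset correlation and did not pass with an estimated correlation (adjusted p = 0.747 for the Ikbkb and 0.855 for the Irf1 deletion). Over the 35 splits of the Ikbkb set, 11 gave at least as many lists past the threshold as the 11 of the real split (highest other 14). In the Irf1 set 25 of 35 gave at least the real 7 (highest other 17). All 34 other splits in each set put at least 1 list past the threshold at the preset correlation. Chance therefore cannot be excluded in either. For the type I median itself, 12 of 35 splits in the Ikbkb set gave 1 at least as large in size (largest other 1.365). In the Irf1 set 9 of 35 did (largest other 0.817). With the T and NK cell score as a covariate the type I median kept 39.1% of its size in the Ikbkb set and 31% in the Irf1 set. Less RNA of T and NK cells, or less interferon from them, may be a part of the difference. Anything else that varied with that score between libraries cannot be told apart from these. Without Ikbkb control replicate 3 it kept 31.7% in the Ikbkb set, and without Irf1 control replicate 4 it kept 53.5% in the Irf1 set. A single unusual control and a real effect that such a library showed more of cannot be told apart with 4 libraries per group. In the Ikbkb set, leaving out control replicate 3 also unbalanced the cDC1 RNA of both groups, which cannot be told apart either. With the cDC1 score as a covariate the type I median kept 95.1% of its size in the Ikbkb set and 112.6% in the Irf1 set. An effect of the deletions on interferon responses stays open, as the T and NK cell covariate left medians of -0.31 and -0.15 and the sort gates are not given in the sources used here.

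Irf1 was not detectably lower in the libraries labelled Irf1-deleted (0.836-fold, 95% interval 0.462 to 1.51), while Ikbkb was lower in those labelled Ikbkb-deleted before adjustment (0.578-fold, 0.358 to 0.934) but not after it (edgeR adjusted p = 0.988) or by exact permutation (p = 0.0857), and its log2 fold change of -0.79 was -0.31 without control replicate 3. RNA of other cells may hide the loss, in which case each gene should rise less steeply with summed cDC1 CPM in deleted libraries, and the slopes per 1000 cDC1 CPM were 49.5 CPM in deleted and 40.9 CPM in control libraries for Irf1 (exact permutation p of the difference 0.8) and 1.12 and 7.65 CPM for Ikbkb (exact permutation p 0.971), which with 4 libraries per group leaves this open. Without the library labelled Irf1-deleted replicate 1, Irf1 averaged 122.1 ± 23.1 CPM over the 3 left against 198.9 CPM in controls (exact permutation p = 0.143), so a wrong label there may explain a part and cannot be told apart from variation between libraries. That library also had the highest summed cDC1 CPM of the Irf1 set, 5207.5, with Irf1 control replicate 2 next at 3415.5. A higher content of cDC1 RNA cannot be told apart from a wrong label either. Reads outside the floxed exons, which the labels do not name, and incomplete deletion, the biological explanation, were not tested.

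The control groups differed in 2018 genes. Only the real split of the 35 gave as many, with 192 in the highest other split. That is the strongest outcome that 35 splits can give, and it makes chance an unlikely account without excluding it. Of these genes 98.9% had the same sign between both deleted groups, which share no library with the controls. By their labels the deleted and control libraries of a set target the same gene. This share therefore cannot separate the floxed genotype from other differences of the sets, and line, day and run cannot be told apart. Another scaling left at least 1882 genes, so the count did not rest on the choice of TMM. Each of these methods applies 1 factor per library, so an error that they share was not tested. TMM factors ran from 0.819 to 1.003 in the Ikbkb set and from 1.025 to 1.104 in the Irf1 set. More fibroblast and endothelial RNA in the Irf1 set stays open, since 62.2% of the genes went in the direction of their relation to that score within groups against 55.9% of all genes, and this does not decide between RNA of other cells and other differences of the sets.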

How the results depend on the processing

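The covariates, the robust fit and the fit without the control library least like its group in each set were chosen only after seeing the data, and the other alternatives were planned.

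Both deletions and their difference kept 0 calls under both other scalings, both other filters, limma voom, a 1.5-fold minimum, every covariate and the robust fit, and edgeR with the 8 libraries of a set alone called 0 in either deletion. DESeq2 called 38, 6 and 12, of which 32, 5 and 9 had a count of 0 in at least 2 libraries. Shared calls were 0 with RLE scaling, the strict filter, DESeq2, each set alone and each library left out, and were not computed under the others. Between the control groups the count was 1199 with no filter, 3171 with DESeq2, 4130 with limma voom, 1069 with the 8 libraries alone and 33 with the 1.5-fold minimum, which is lower because it asks for more than a change. Both fold changes correlated at 0.223 under the strict filter, which drops genes with few counts, and at 0.18 with each set alone. Except for these constructions, the cause was not tested.

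With an estimated correlation 0 lists passed in either deletion, and with fry 0 lists passed in either. Both camera runs differed only in the correlation setting, so the loss of lists with an estimated correlation follows from it. The estimate was 0.687 for type I interferon genes and 0.64 for interferon-gamma genes, against the preset 0.01. Fry does not use the preset correlation either, and whether that is why fewer lists passed with fry was not tested. With the T and NK cell score 5 lists passed for the Ikbkb deletion, and the T and NK cell markers themselves had a median of 0.066, which that covariate removes by construction. Without the 2 least similar controls 5 lists passed for the Ikbkb deletion and 3 for the Irf1 deletion. In that fit the medians of DC maturation (0.205, adjusted p = 0.566), MHC class I (0.091, 0.68) and stress genes (0.062, 0.776) in the Ikbkb deletion were positive and did not pass. T and NK cell markers in the Irf1 deletion had a median of -0.084 and did not pass (0.913).

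Leaving out each library in turn gave 0 to 1 calls for the Ikbkb deletion (1 without Ikbkb-deleted replicate 2), 0 for the Irf1 deletion, 0 to 1 for their difference (1 without Irf1 control replicate 3), 782 to 2404 between the control groups and a correlation of 0.013 to 0.096. Lists past the threshold ran from 5 to 13 for the Ikbkb deletion and from 4 to 11 for the Irf1 deletion. Medians ran from -0.938 to 0.206 for DC maturation, from -0.522 to 0.091 for MHC class I and from -0.533 to 0.062 for stress genes in the Ikbkb deletion, with the highest of each without control replicate 3. T and NK cell markers in the Irf1 deletion ran from -1.464 to -0.088, the latter without control replicate 4.

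Of the values for single genes, 2468 kept their direction and side of the threshold or stayed within the spread, 208 moved, 9 newly passed, 2 no longer passed and 0 reversed. Of those for lists, 436 were the same, 57 moved, 95 no longer passed, 33 newly passed and 9 reversed. Whether depth limits the calls was not tested.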

Other observations

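Both relations between gene levels, the splits by unadjusted p and the genes of other tissues were chosen only after the results were seen.

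Interferon-gamma-inducible RNA may rise with T and NK cell RNA across libraries. The relation held in both sets over all 8 libraries, with an exact permutation p of at most 0.00211. In the Ikbkb set r was 0.661 without the 2 libraries farthest from the median and did not pass (exact permutation p = 0.132, n = 6). Both lists were measured in the same libraries, so the values do not tell interferon made by T and NK cells in the tumour from RNA of these cells carried into the libraries. Another difference between libraries that moved both lists together cannot be told apart from these, as no other list was tried.

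Irf1 RNA could rise with cDC1 RNA. In the Ikbkb set r was 0.721 (exact permutation p = 0.0368, adjusted p = 0.0491) and rho 0.667 (exact p = 0.0831, adjusted p = 0.111), and r was 0.645 without the 2 libraries farthest from the median (exact p = 0.179). In the Irf1 set r was 0.679 (exact permutation p = 0.0664, adjusted p = 0.0664) and rho 0.595 (exact p = 0.132, adjusted p = 0.132), and r was 0.624 without those 2 (exact p = 0.196). About the group means r was 0.854 in the Ikbkb set and 0.747 in the Irf1 set. The relation over all 8 libraries did not pass in both sets, so it stays a hypothesis.

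The real splits called 0 genes for both deletions and for their difference, so all 35 splits in each set and all 100 regroupings call at least as many, and that comparison decides nothing. Another split called at most 3 genes in the Ikbkb set and 0 in the Irf1 set, and another regrouping at most 2. At an unadjusted p under 0.05, 30 of 35 splits gave at least the 769 genes of the Ikbkb deletion (highest other 2343) and 14 of 35 at least the 419 of the Irf1 deletion (highest other 1184), so chance cannot be excluded for either count. Of 1225 pairs of splits, 164 gave a correlation between both deletions at least as large in size as 0.089, with 0.158 the highest, so chance cannot be excluded there.

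Keratin genes of skin were present in a few libraries. Krt14 measured 572 CPM in Irf1-deleted replicate 3 and 46.6 CPM in the library labelled Irf1-deleted replicate 1, and Krt5 160 and 19.6 CPM in the same libraries. The muscle gene Acta1 ran from 15.1 to 504 CPM in the 8 libraries of the Ikbkb set, highest in control replicate 3, and from 0.767 to 4.30 CPM in the 8 of the Irf1 set, so the sets did not overlap (log2 fold change between the controls -6.30, SE 0.98, edgeR adjusted p = 0.00505). It is among the genes that differed between the control groups. The immunoglobulin gene Igkc measured 625 CPM in Ikbkb control replicate 3.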
